A study of Mus musculus with 7 samples.

How the data were processed

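Spatial transcriptomes of 7 coronal mouse brain sections were measured with the 10x Genomics Visium kit, in which barcoded spots under a section capture polyadenylated RNA. Per the labels, male C57BL/6J mice received 10 µL of saline (sham), heme bound to albumin (heme-albumin, at 0.30, 1.25, 5.0 or 10 nmol) or heme bound to the plasma protein hemopexin (heme-hemopexin, at 10 nmol) through a 33G needle into the right striatum, and 1 mouse had an untouched brain. Per the labels' protocols, mice were perfused with phosphate-buffered saline and brains were frozen, cut at 10 µm, fixed in methanol, stained with haematoxylin and eosin and permeabilized for 6 min, and the cDNA was amplified for 15 cycles and sequenced on an Illumina NovaSeq. The interval between injection and brain removal is not given in the sources used here.

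Per the submitters' processing notes, reads were processed with Space Ranger 1.1.0 against GRCm38.p6, and Scanpy 1.6.0 was also used, with no role stated. The deposited matrices hold UMI counts per gene and spot for spots under tissue, per the file headers, and were used without further scaling by the authors. Each section had a further copy of its matrix with the same entries, which was not used here. The deposited sequencing summaries give the Q30 of UMI bases, the sequencing saturation and the reads under tissue as fractions, per the file headers, and these are printed as percentages. The labels name no sequencing batch, and batches were inferred from the Q30 after the values were seen. Of the 26124 gene IDs in the summed tables, 26090 matched the GENCODE vM21 annotation of GRCm38, from which coordinates were taken. Genes that share reads with near-identical copies (the hemoglobin genes, Hist2h2aa1, Gstp1) are uncertain, because how such reads were counted is not stated.

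Counts were summed per section over all tissue spots and over the spots of named regions. The main test was edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, R 4.3.3, limma 3.58.1) on genes with at least 1 CPM (UMI counts scaled to equal section totals) in at least 2 sections, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had an intercept, log2(1 + nmol heme-albumin), and 1 indicator each for the heme-hemopexin and the untouched section. Log2 changes along the dose are the fitted difference between 0 and 10 nmol, the carrier contrast is the heme-hemopexin section against the line at 10 nmol, and the injection contrast is the line at 0 nmol against the untouched section. Each group has 1 section and no replicate, so p-values rest on the scatter of 5 sections around the dose line (3 residual degrees of freedom), and the heme-hemopexin and untouched sections are assumed to vary like those 5. EdgeR also shares the variance between genes, with a prior of 3.97 to 8.41 degrees of freedom in the whole section, striatal and cortical fits. In the myelin gene regions the prior was 171, so p-values there rest almost wholly on a variance pooled over genes. Values after ± are standard errors. The direct contrast of the sections at 10 nmol gives the 10 nmol heme-albumin section a term of its own, so its p-values rest on the scatter of the other 4 sections of the dose line (2 residual degrees of freedom). Folds between the counts of 2 sections carry no p-value, and their exact 95% intervals (Poisson for CPM, binomial for shares and ratios) cover counting error only. A count of 0 was set to a floor of 3 counts per section for folds.

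The 26 gene lists were written before the data were examined, as were the design, the rule for naming genes and the alternatives named below, apart from those said to be added later. They cover heme and iron handling, NRF2 and oxidative stress, interferon, NF-kB and cytokine genes, complement and antigen presentation, microglia, damage-associated microglia, monocytes and macrophages, neutrophils, T and NK cells, reactive and homeostatic astrocytes, oligodendrocytes and their precursors, neurons, striatal neurons, endothelial cells, mural cells, fibroblasts and meninges, matrix and wound genes, endoplasmic reticulum and heat stress, immediate early genes, proliferation, ependyma and choroid plexus, erythrocytes and mitochondrial transcripts. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. For pairs of sections, a list's median was placed among 10000 random lists of the same size matched on expression. Named genes were, per edgeR result, the 10 rising and 10 falling genes with the largest absolute log2 change among those with adjusted p below 0.05 and a mean CPM of at least 5, plus Hmox1 and Hpx, and the 2 members with the largest absolute change from each described list. For pairs, the same genes were named along with the 10 largest folds each way among genes with at least 100 UMIs in both sections. Predicted and ribosomal protein genes stayed in the counts but were passed over in naming. The genes that differed with the Q30 of the sections (such as Coro1b, Gstp1 and Nme2) were singled out after their values were seen.

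For clustering (Python 3.11.15, scikit-learn 1.9.0, igraph 0.11.9), counts per spot were scaled to 10000, log-transformed and centred per gene and section, over 2000 variable genes without the response lists (heme and iron to reactive astrocytes), with 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from markers fixed in advance and are called regions after their leading genes, since a spot can hold several cells, for which reason no doublet caller was run. Shares of spots with a Hmox1 UMI were taken after thinning each spot to 2000 UMIs. The Hmox1 centre of a section was the spot with the highest Hmox1 CPM within 500 µm, and list CPM (without Hmox1) was compared between spots within 500 µm of it and spots beyond 2000 µm, at a spot pitch of 100 µm. On simulated counts for the whole section test, 88% of 100 genes changed by log2 1 and 100% of 100 genes changed by log2 2 were recovered, with 14 false calls among 13425 unchanged genes. For the striatal region these values were 81%, 98% and 10 of 13083, and for the comparison of regions within sections 70%, 98% and 9 of 13391.

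The alternatives were DESeq2 1.42.0, scaling to total counts, no expression filter, a linear or ranked dose, the untouched section as dose 0, counts thinned to the smallest section, k-means regions, no centring, Leiden resolution 0.5, thinning to 5000 UMIs, other radii, and leaving out each section in turn. A fit of striatal minus cortical gene regions within each section, in which a change shared by the whole section cancels, was added after the data were seen, as were the direct contrast of the sections at 10 nmol, a linear and a ranked dose in the striatal region, the whole striatal carrier result, and profiles without spots of the RNA-poor cluster or with the centre placed below the cortex. So were simulated counts on the fitted striatal dose line, which give the opposite calls of the dose trend and the carrier contrast that arise from their common line.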

Results

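The data are UMI counts in 7 coronal sections, 1 per group: an untouched brain, a saline sham injection, heme-albumin at 0.30, 1.25, 5.0 and 10 nmol, and heme-hemopexin at 10 nmol. Heme is the iron porphyrin freed from hemoglobin when blood enters the brain, and hemopexin is the plasma protein that binds it most tightly. Sections held 2427 to 2953 spots under tissue and 32246643 to 49577212 UMIs. In the order untouched, saline, 0.30, 1.25, 5.0 and 10 nmol heme-albumin and heme-hemopexin, the median UMIs per spot were 11156, 17871.5, 18510, 17069, 14486.5, 11629 and 13736. Sequencing saturation ran from 63.6% to 76.3%. The labels name no sequencing batch, but the Q30 of UMI bases split the sections, at 96.9% to 97.1% for saline and the 3 lower doses and 97.2% for the untouched brain, against 94.8% for 10 nmol heme-albumin and 94.9% for heme-hemopexin. The sections on each side are treated here as a batch. Values within a batch are those without the 10 nmol section for the dose trend, and the direct contrast of the sections at 10 nmol for the carrier. Saline and the untouched brain are on the same side by Q30 but differ in reads under tissue, at 67.5% in the untouched section against 84.8% to 93.2% in the others.

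Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was higher with every step in the amount of heme given on albumin, and far lower when the same amount was given on hemopexin. Hmox1 lies on chromosome 8 at 75093621 to 75100589 on the plus strand (GRCm38). Over whole sections it was at 4.00 CPM (95% interval 3.34 to 4.75) in the untouched brain and 12.0 (11.1 to 13) after saline. At 0.30, 1.25, 5.0 and 10 nmol heme-albumin it was at 25.5 (24.1 to 27.0), 101 (98.1 to 104), 140 (137 to 144) and 194 (190 to 199) CPM, and with 10 nmol heme-hemopexin at 39.8 (37.9 to 41.8). In the striatal gene region, led by Penk and Adora2a, it went from 2.91 CPM (14 UMIs) after saline to 409 CPM (2280 UMIs) at 10 nmol heme-albumin, against 33.8 CPM (244 UMIs) with heme-hemopexin. After thinning to 2000 UMIs, the share of spots with a Hmox1 UMI was 0.874% (95% exact interval 0.555% to 1.31%) in the untouched brain and 1.76% (1.30% to 2.33%) after saline. At the 4 doses it was 4.42% (3.63% to 5.32%), 13% (11.7% to 14.4%), 17.4% (15.9% to 18.9%) and 20.5% (19.0% to 22.0%), and with heme-hemopexin 5.45% (4.65% to 6.34%). Without thinning the shares were 4.55%, 8.27%, 15.6%, 34.8%, 42.2%, 46.5% and 22.0% in the same order. Thinning left out 47, 60, 219, 52, 58, 171 and 56 spots.

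**Figure D1:**
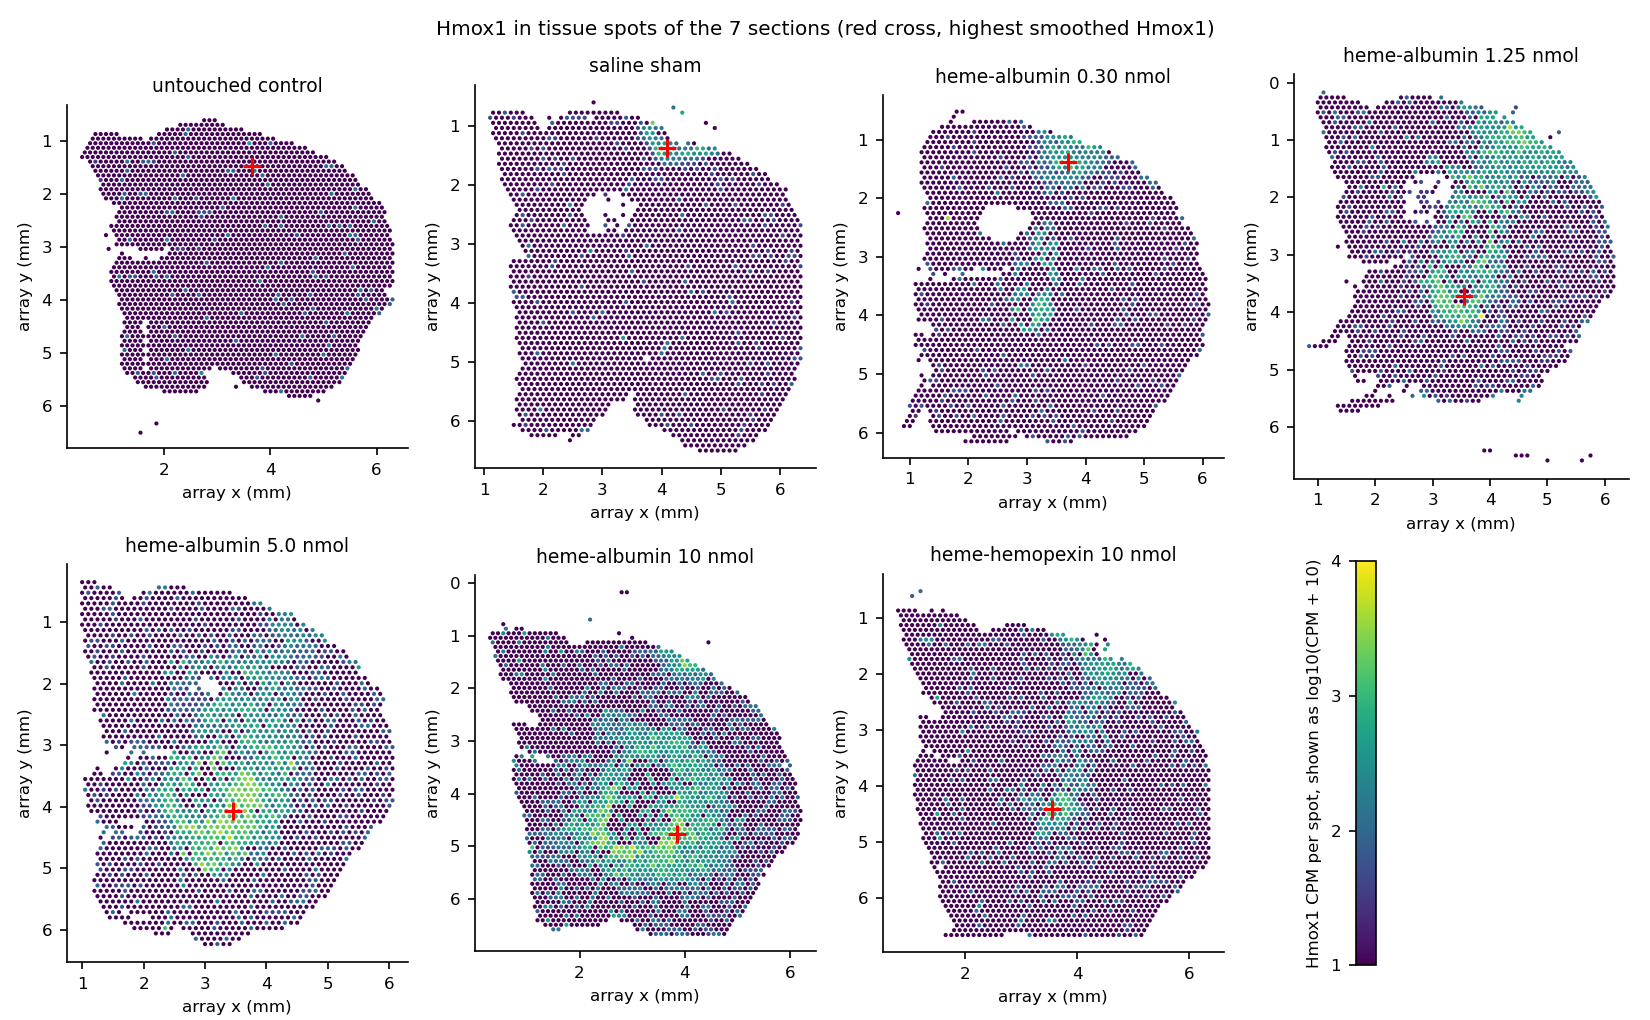
Hmox1 in each tissue spot of the 7 sections, drawn at array positions in mm and coloured by log10(CPM + 10), with a red cross at the highest smoothed Hmox1. The share of spots with a Hmox1 UMI after thinning went from 1.76% after saline to 20.5% at 10 nmol heme-albumin and was 5.45% with heme-hemopexin.

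The first comparison asks which genes follow the heme-albumin dose in the striatal gene region. The striatum was injected, but in none of the 6 injected sections did the spot at the Hmox1 centre belong to this region, so the most affected spots can lie outside it. The rising genes included Hmox1, the chemokine genes Ccl2 and Ccl7, the wound gene Timp1 and the reactive astrocyte gene Lcn2. The microglial genes Siglech, Tmem119 and P2ry12 fell, as did Hes5, a Notch target of astrocytes and progenitors. Of 13504 genes, 276 rose and 167 fell, and the genes kept when any section was left out included Hmox1, Ccl2, Timp1, Ptx3, Flnc, Fosl1, Hes5, Tmem119, P2ry12, Selplg and Aspa. The fit without the 10 nmol section, whose dose line rests on sections with the higher Q30, called 117 genes (96 rising), of which 87 were among the 443, and fits without another section called 229 (without 1.25 nmol), 266 (without 0.30 nmol), 329 or 362.

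Hmox1 rose by 4.99 ± 0.77 on the log2 scale from 0 to 10 nmol (edgeR adjusted p = 0.00716), and by 6.43 without the 10 nmol section. Ccl2, the chemokine that draws monocytes (chromosome 11, 82035571 to 82037453), rose by 4.60 ± 0.59 (edgeR adjusted p = 0.00272), and was at 3.12 CPM after saline, 184 at 5.0 nmol and 166 at 10 nmol. The inhibitor of matrix proteases Timp1 rose by 4.55 ± 0.72 (edgeR adjusted p = 0.00765), and was at 3.33 CPM after saline and 512 at 10 nmol. Here and below, fitted changes can be smaller than the CPM of the sections imply, since the line at 0 nmol need not equal the saline section. Ptx3, a soluble pattern recognition protein, rose by 4.29 and reached 180 CPM, and the chemokine Ccl7 rose by 3.77 (3.70 and no longer called without 0.30 nmol). The cross-linking enzyme gene Tgm1 rose by 3.71, and by 4.14 without a call when the 10 nmol section was left out. Lcn2, a siderophore-binding protein of reactive astrocytes, rose by 3.54, from 7.07 CPM to 522, and was not called without 5.0 nmol (3.54) or without 10 nmol (4.24). The actin cross-linker Flnc rose by 3.53 ± 0.39 (edgeR adjusted p = 0.00147) and the AP-1 member Fosl1 by 3.45. Hist2h2aa1, a histone gene with a near-identical copy, had the largest fitted rise at 8.75, but was at 1.88 CPM at 5.0 nmol, 40.6 at 10 nmol and 57.8 with heme-hemopexin, the 2 sections with the lower Q30, and fell to 2.63 with no call without the 10 nmol section. Hpx, the gene of hemopexin itself, rested on 5 to 8 UMIs in the other injected sections and 24 at 10 nmol, and its change of 1.78 ± 0.67 (edgeR adjusted p = 0.206) became -0.13 without the 10 nmol section.

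Among falling genes, Hes5 fell by 2.78 ± 0.22 on the log2 scale (edgeR adjusted p = 0.000368), from 40.3 CPM after saline through 24.7, 18.5 and 10.6 to 5.20 at 10 nmol. The microglial genes Siglech, Tmem119 and P2ry12, which encode a lectin, a transmembrane protein and the purine receptor that guides microglial processes, fell by 2.94, 2.5 and 2.47. Tmem119 (chromosome 5, 113793729 to 113800516) went from 19.96 CPM to 6.10 (edgeR adjusted p = 0.00492) and P2ry12 from 19.1 to 5.20 (edgeR adjusted p = 0.00825). Siglech was not called without the 10 nmol section (-2.53), whereas Tmem119, P2ry12 and Selplg, which encodes the P-selectin ligand, were called without it (-2.90, -3.70 and -2.61). Aspa, an aspartoacylase of oligodendrocytes, fell by 1.93. The choroid plexus gene Kl fell by 2.23 and lost its call without 1.25 nmol (-2.24), 10 nmol (-1.40) or saline (-2.12). The Notch regulator Nrarp fell by 1.93, the respiratory gene Cox8b by 1.76 and the clock gene Per2 by 1.64. None of these 3 was called without the 10 nmol section (-1.25, -2.0 and -1.36), nor was Per2 without saline (-1.35).

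**Figure D2:**
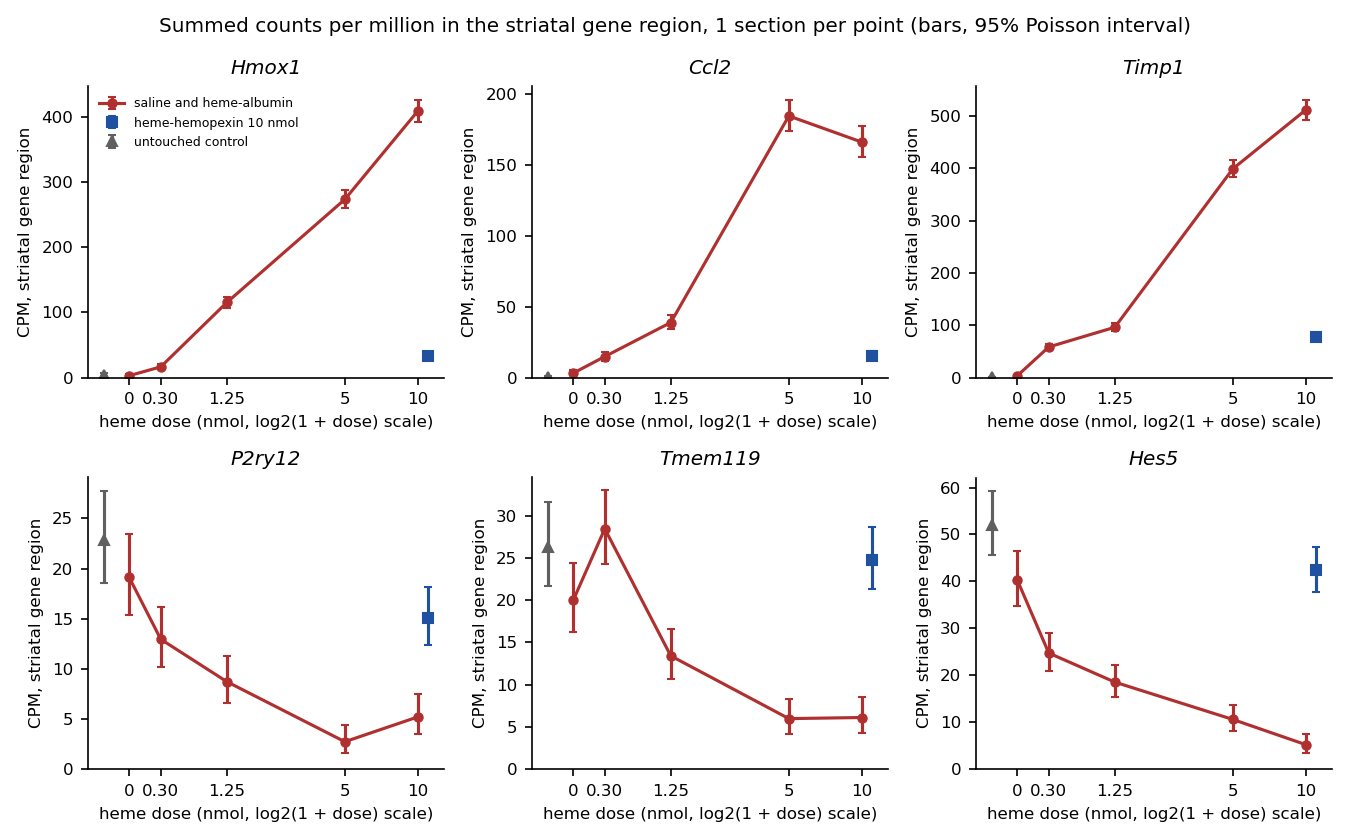
CPM in the striatal gene region (vertical axis) by heme-albumin dose in nmol (horizontal axis) for Hmox1, Ccl2, Timp1, P2ry12, Tmem119 and Hes5, with 95% Poisson bars and separate points for heme-hemopexin and the untouched brain. Hes5 went from 40.3 CPM after saline to 5.20 at 10 nmol heme-albumin and was at 42.3 with heme-hemopexin.

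The gene lists give the same division in the striatal gene region. Each p beside a list is the edgeR-based camera test adjusted over lists, and none of the 14 lists below 0.05 kept its call with an estimated correlation, where the adjusted p ran from 0.105 (matrix and wound genes) to 0.819 (interferon). The reactive astrocyte list had a median of 1.83 (adjusted p = 3.55e-24, adjusted p = 0.197 with an estimated correlation), and 12 of its 24 genes rose (18 adjusted over the list alone). Matrix and wound genes had a median of 1.66 (adjusted p = 2.43e-19), and 7 of 14 rose (8 adjusted over the list alone), among them Timp1 and Tnc, an extracellular matrix glycoprotein. NF-kB and cytokine genes had a median of 1.47 (adjusted p = 7.91e-13), with 4 of 19 rising (11 adjusted over the list alone), including Ccl2 and Ccl7. In the NRF2 list 6 of 21 genes rose (13 adjusted over the list alone, median 0.53, adjusted p = 9.54e-11). The metallothionein Mt2 rose by 2.78 ± 0.36 (edgeR adjusted p = 0.00278) from 199 CPM to 2306. In the heme and iron list 2 of 19 rose (5 adjusted over the list alone, median 0.29, adjusted p = 0.00104). The damage-associated microglia list rose in 6 of 16 genes (9 up and 1 down adjusted over the list alone, median 0.66, adjusted p = 1.83e-12), with the secreted phosphoprotein Spp1 at 2.35 ± 0.23 (edgeR adjusted p = 0.000787). In the monocyte and macrophage list 4 of 14 rose (7 adjusted over the list alone, adjusted p = 2.79e-12). The macrophage arginase Arg1 had 0 UMIs after saline and 1, 10, 28 and 84 at the 4 doses, and the scavenger receptor Msr1 rose by 2.82 (edgeR adjusted p = 0.0448). In the neutrophil list 1 of 4 rose (2 adjusted over the list alone, median 1.45, adjusted p = 0.00634).

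In the opposite direction, 7 of 16 microglia genes fell and none rose (12 adjusted over the list alone, median -1.02, adjusted p = 4.99e-14, adjusted p = 0.197 with an estimated correlation), so microglial identity genes and damage-associated genes moved apart. Mitochondrial transcripts fell in 8 of 10 genes (10 adjusted over the list alone, median -0.64, adjusted p = 4.45e-12). The mitochondrial share of all UMIs was 14.5% at 10 nmol and 15.3% with heme-hemopexin, against 18.8% to 21.5% in the other injected sections. Among the injected sections this list thus also moves with the Q30. The untouched section had the highest Q30 (97.2%) but the lowest share (13%), so the share does not follow the Q30 over all sections. Striatal neuron genes fell in 2 of 12 (5 adjusted over the list alone, median -0.32, adjusted p = 0.000206, adjusted p = 0.296 with an estimated correlation), with the dopamine receptor Drd2 at -0.51 (edgeR adjusted p = 0.0425). Oligodendrocyte precursor genes fell as a list (median -0.42, adjusted p = 0.0128) with 0 of 7 called (1 adjusted over the list alone), as did ependyma and choroid plexus genes (median -0.93, adjusted p = 3.48e-05) with 1 of 9 (5 adjusted over the list alone). The interferon list passed (median 0.47, adjusted p = 0.0195) with 0 of 23 genes called over all genes and 0 adjusted over the list alone. Its chemokine Cxcl10 was at 277 CPM at 5.0 nmol and 60.7 at 10 nmol.

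The lists that did not pass in the striatal gene region, with the camera test on the edgeR design, were complement and antigen presentation (median 0.15, adjusted p = 0.0596), T and NK cells (0.09; 0.971), homeostatic astrocytes (-0.11; 0.891), oligodendrocytes (-0.30; 0.783), endothelial cells (0.28; 0.798) and mural cells (-0.10; 0.783). Neither did endoplasmic reticulum and heat stress (0.13; 0.058), immediate early genes (-0.27; 0.402), proliferation (0.12; 0.808), erythrocytes (0.98; 0.058), all neurons (-0.01; 0.783) and fibroblasts and meninges (-0.09; 0.783), and the last 2 had a test pointing up against a negative median. Single members of these lists were called, such as the antigen presentation gene H2-Ab1 (2.34, edgeR adjusted p = 0.0337), the immediate early gene Egr1 (-1.54 ± 0.20, edgeR adjusted p = 0.00272), the endoplasmic reticulum and heat stress genes Atf3 (3.07, edgeR adjusted p = 0.0118) and Hspa1a (1.55, edgeR adjusted p = 0.0361), the contractile gene Tagln (3.37, edgeR adjusted p = 0.0112) and the pericyte gene Higd1b (-1.46, edgeR adjusted p = 0.0152). The oligodendrocyte genes Gjb1 (2.15, edgeR adjusted p = 0.0284) and Ugt8a (-1.30, edgeR adjusted p = 0.049) moved apart. Fry called 3 of the 26 lists: heme and iron (adjusted p = 0.0351), oligodendrocyte precursors (0.0266) and matrix and wound genes (0.0266).

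**Figure D3:**
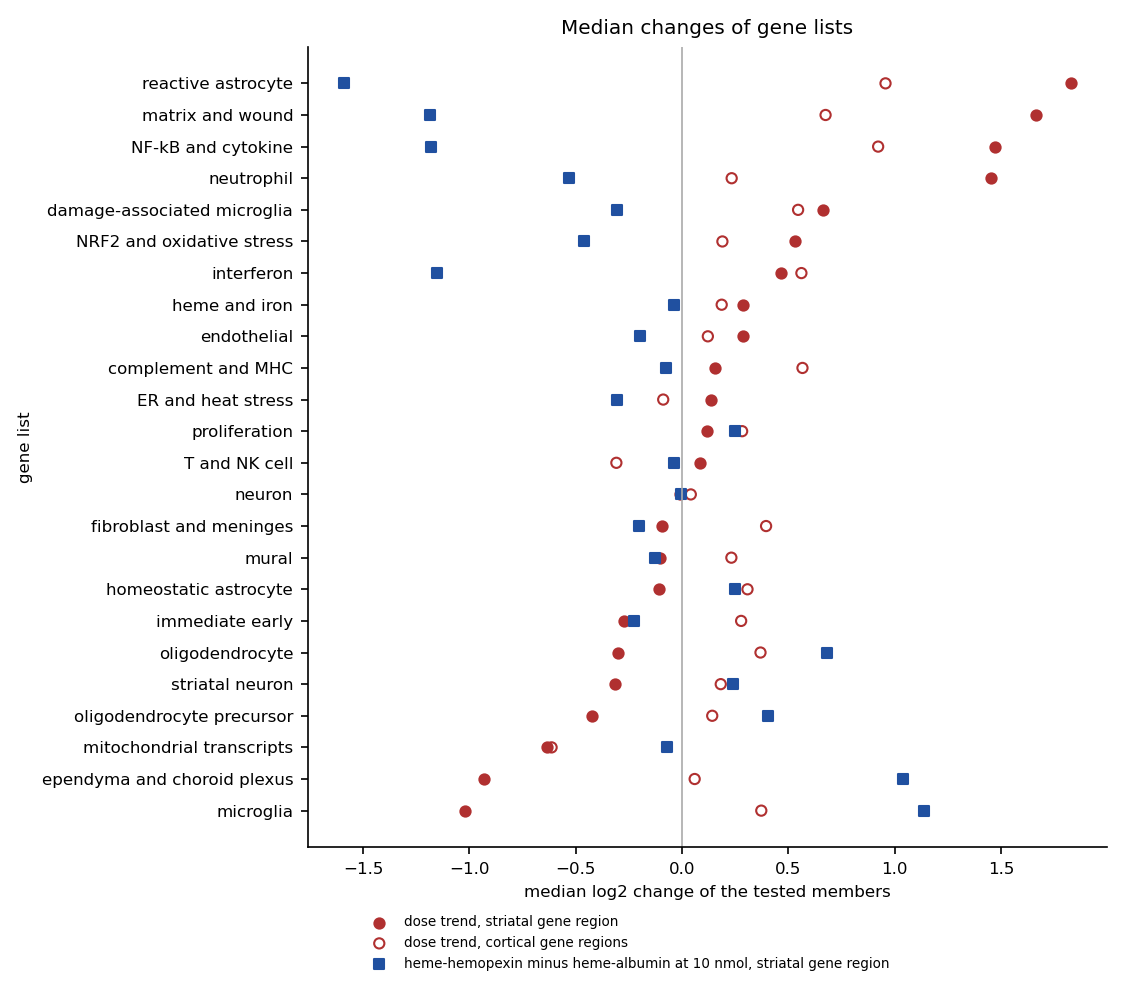
Median log2 change (horizontal axis) of 24 of the 26 gene lists, without erythrocytes and monocytes, which hold genes at 0 counts in a section, for the dose trend in the striatal and the cortical gene regions and for heme-hemopexin against heme-albumin in the striatal gene region. The reactive astrocyte median was 1.83 along the dose and -1.59 for the carrier, and the microglia median -1.02 and 1.14.

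Over whole sections, the rising genes included Nes, Flnc, Trf and Lcn2, and the falling genes Bdnf, Homer1 and Egr3, which neuronal activity induces, together with P2ry12 and Hes5. Of 13737 genes 77 rose and 15 fell with edgeR, and 2828 had an unadjusted p below 0.05. These calls depend on single sections: 0 genes were called without 0.30 nmol (1958 unadjusted), 0 without 10 nmol (1618 unadjusted), 3 without saline, 23 without 5.0 nmol and 202 without 1.25 nmol (92 shared), and DESeq2 called 700 (399 rising). Scaling to total counts gave 388 genes, 94.6% of them rising against 83.7% with TMM, and shifted the median of all genes by 0.13. None of the named genes of this trend was called in every fit that left out a section. Lcn2 rose by 2.80 ± 0.40 on the log2 scale (edgeR adjusted p = 0.0462), from 21.9 CPM to 252, and Flnc by 3.24 ± 0.47 (edgeR adjusted p = 0.0462). Nes, the intermediate filament nestin of reactive and progenitor cells, rose by 2.5 ± 0.19 (edgeR adjusted p = 0.0179), the sphingosine phosphate receptor S1pr3 by 2.41, the tubulin Tuba1c by 2.25, the chromatin protein Hmga1 by 2.09, the TWEAK receptor Tnfrsf12a by 2.01 and S100a11 by 1.87. Gpnmb, a lysosomal glycoprotein of lipid-loaded macrophages, rose by 3.59 ± 0.34 (edgeR adjusted p = 0.0182), the transferrin gene Trf by 1.45, Tnc by 2.01, Hspa1a by 1.6 and the water channel gene Aqp4 by 0.81. Hist2h2aa1 (6.39) and Coro1b (2.95) were also called. Both were high in both sections with the lower Q30, with a heme-hemopexin change relative to the dose change of 1.09 and 1.53 in the striatal gene region, against 0.152 for Hmox1. Each of these changes is taken from the fitted line at 0 nmol, which need not equal the saline section. Bdnf, the activity-dependent neurotrophin, fell by 1.29, the synaptic scaffold Homer1 by 1.28, Egr3 by 1.19, P2ry12 by 1.06 ± 0.13 (edgeR adjusted p = 0.0326), Nrn1 by 1.00, Plppr5 by 0.82, Tafa1 by 0.79, Gabra2 by 0.78, Hes5 by 0.75 and Ppp2r2b by 0.66. Hmox1 itself had a change of 3.37 ± 0.72 that did not pass (edgeR adjusted p = 0.0853), and so did Hpx (1.1 ± 0.43, edgeR adjusted p = 0.215).

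In whole sections 15 lists passed camera on the edgeR design, and 0 kept the call with an estimated correlation. Reactive astrocyte genes rose in 3 of 23 (19 adjusted over the list alone, median 1.67, adjusted p = 8.1e-25, adjusted p = 0.316 with an estimated correlation). Damage-associated microglia genes rose in 2 of 16 (11 adjusted over the list alone, median 0.68, adjusted p = 1.32e-16, adjusted p = 0.203 with an estimated correlation) and matrix and wound genes in 2 of 14 (10 up and 1 down adjusted over the list alone, median 1.11, adjusted p = 2.45e-12). NRF2 genes rose in 2 of 21 (15 adjusted over the list alone, median 0.43, adjusted p = 1.53e-14, adjusted p = 0.0963 with an estimated correlation) and heme and iron genes in 3 of 19 (6 adjusted over the list alone, median 0.14, adjusted p = 6.5e-08, adjusted p = 0.114 with an estimated correlation), and these were the 2 lists that fry called (0.0163 each). The interferon list had 24 of 24 positive changes and a median of 0.81 (adjusted p = 2.17e-06, adjusted p = 0.480 with an estimated correlation) with 0 genes called. Oligodendrocyte genes rose in 2 of 12 (5 adjusted over the list alone, median 0.35, adjusted p = 6.5e-08), and mitochondrial transcripts had a median of -0.57 (adjusted p = 6.24e-09) with 0 genes called and 9 of 10 adjusted over the list alone. The microglia list did not pass (median -0.11, adjusted p = 0.109). For immediate early genes the median was 0.15 while the test pointed down (adjusted p = 0.734).

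In the cortical gene regions, above the injected striatum, the trend had fewer genes. Bdnf, Homer1 and Egr3 fell, and the apolipoprotein gene Apod and the myelin genes Mobp and Mag rose. Of 13336 genes 9 rose and 8 fell with edgeR (2145 unadjusted), and the fits without a section called 9 (without 0.30 or 10 nmol) to 111 genes (without 5.0 nmol). Of the rising genes 6 also rose in the striatal gene region (0.185 if the lists were independent) and of the falling genes 2 also fell there (0.102), and part of that excess may come from the sections both share. Apod rose by 1.32 ± 0.14 on the log2 scale (edgeR adjusted p = 0.00672), from 144 CPM after saline to 389 at 10 nmol and 367 with heme-hemopexin, and was the 1 named gene of 17 called in every fit that left out a section (1.62 without 10 nmol). The myelin genes Mobp and Mag rose by 0.89 and 0.73, the von Willebrand factor gene Vwf by 1.24, Lars2 by 0.95 and Tspan4 by 0.83. Hist2h2aa1 (5.96) and Gstp1 (2.03), genes high in both sections with the lower Q30, were called too. Homer1 fell by 1.33, Bdnf by 1.28, the interneuron peptide gene Cort by 1.21, Egr3 by 1.15 ± 0.12 (edgeR adjusted p = 0.00672), the pentraxin Nptx2 by 0.92, Galnt9 by 0.91, Nrn1 by 0.86 and Tmem126a by 0.65, none of them called without the 10 nmol section. Scaling to total counts called 66 genes, 84.8% of them rising against 52.9%, and moved the median of all genes by 0.18. DESeq2 called 180 with 23.3% rising, and regions drawn without centring 73 with 68.5% rising. Hmox1 (1.49 ± 0.78, edgeR adjusted p = 0.37) and Hpx (0.94, edgeR adjusted p = 0.381) did not pass. The microglia list went up here, with a median of 0.37 (adjusted p = 6.2e-05, adjusted p = 0.347 with an estimated correlation), 0 of 16 genes called and 8 adjusted over the list alone. The damage-associated microglia (median 0.55, adjusted p = 5.96e-09, adjusted p = 0.328 with an estimated correlation), oligodendrocyte (0.37; 4.48e-08; 0.229) and reactive astrocyte lists (0.96; 1.9e-08; 0.383) went up as well.

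In the myelin gene regions, led by Mog and Mbp, interferon and reactive astrocyte genes rose with the dose, and the microglial genes Selplg and Tmem119 fell. Of 14042 genes 95 rose and 25 fell with edgeR (1044 unadjusted), and fits without a section called 59 (without saline), 72 (without 0.30 nmol) and 99 to 139 genes. The region joins clusters of unequal depth, since the RNA-poor cluster led by Mbp held 196 spots against 64 of the one led by Mog at 0.30 nmol and 113 against 97 at 10 nmol, but fewer in the other sections. The edgeR p-values here rest almost wholly on a variance pooled over genes, and little on the scatter of each gene between sections. The alarmin genes S100a8 and S100a9 rose by 5.13 and 4.45, and the metalloproteases Mmp12 and Mmp3 by 6.78 and 6.12, but without the 10 nmol section S100a8 was at 0.47, S100a9 at -0.14, Mmp3 at 0.54 and Mmp12 at 3.59, none of them called. Coro1b (6.97) and Hist2h2aa1 (8.80), high in both sections with the lower Q30, and Ms4a6c (4.07) also lost their calls (6.24, 2.33 and 3.89). The erythrocyte genes Hbb-bs (4.15) and Hba-a1 (3.90), near-identical to other hemoglobin genes, went to -0.83 and -0.72 without 5.0 nmol, and lost their calls without 0.30 nmol (3.87 and 3.43). Phf11b rose by 3.85 and lost its call without saline (2.88). Hmox1 rose by 1.80 (edgeR adjusted p = 0.00402), but by 0.32 without saline and 1.5 without 0.30 nmol, with no call. Selplg fell by 1.81 (edgeR adjusted p = 0.000175) and Tmem119 by 1.55, and neither was called without saline (-1.51 and -1.38). The hypothalamic peptide gene Pmch (-3.96) went to 0.070 without saline. Nkx2-9 (-3.27), Unc13c (-2.17) and Lypd1 (-2.14) fell but were not called without saline (-1.51, -1.0 and -1.91). Ccdc88a (-1.58), Gnpda2 (-1.56), Lrrc17 (-1.41) and Lbhd2 (-1.35) fell but were not called without 10 nmol (-0.90, -1.33, -0.66 and -0.77). The interferon list rose in 15 of 25 genes (19 adjusted over the list alone, median 1.72, camera on the edgeR design, adjusted p = 1.33e-27, adjusted p = 0.167 with an estimated correlation) and the reactive astrocyte list in 11 of 24 (15 adjusted over the list alone, median 1.28, adjusted p = 1.33e-27, adjusted p = 0.082 with an estimated correlation). The microglia list had a median of -0.74 (adjusted p = 2.14e-05, adjusted p = 0.330 with an estimated correlation), with 1 of 16 genes falling (4 adjusted over the list alone). DESeq2 called 32 genes, 46.9% of them rising against 79.2%.

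Heme-hemopexin was compared with heme-albumin at the same 10 nmol, which asks whether the protein that carries the heme changes the response. In the striatal gene region Ccl2, Ccl7, Ptx3 and Flnc, which followed the heme-albumin dose, were lower with hemopexin. Hes5 and the microglial genes Siglech, Tmem119, P2ry12 and Selplg were higher. Of the genes tested, 46 were higher and 98 lower (edgeR), 1518 had an unadjusted p below 0.05, and 89 of the lower genes were among those that rose with dose (2.00 if the lists were independent) and 28 of the higher genes among those that fell (0.569). Both contrasts use the fitted dose line, which by itself sets calls against each other. In 20 simulated sets with no change in any gene the opposite calls averaged 0.20 each way. With the dose slopes of the called genes kept and no carrier difference they averaged 1.45 and 1.1 (at most 4 and 3). Part of the excess may still come from the sections both contrasts share. The direct contrast of the sections at 10 nmol, which share the lower Q30, called 12 higher and 41 lower genes, 50 of them shared. Fits without a section called 51 genes (without 5.0 nmol) to 272 (without saline), and 85 without 1.25 nmol. DESeq2 called 95, and a linear dose in place of the log scale 3.

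With hemopexin Ccl2 was lower by a log2 change of -4.25 (edgeR adjusted p = 0.0203), at 15.4 CPM against 166, and Ptx3 by -3.92. The matricellular genes Ccn1 (-3.76) and Tnc, Ccl7 (-4.13), Fosl1 (-3.51), the cytokine suppressor Socs3 (-3.36), the lipase inhibitor Angptl4 (-3.18), Scgb3a1 (-3.54) and Flnc (-2.85) were lower as well. Mt2 was lower by -2.18 (edgeR adjusted p = 0.0321), Spp1 by -2.21 (edgeR adjusted p = 0.00501) and Tnfrsf12a by -2.73. Hes5 was higher by 2.81 (edgeR adjusted p = 0.00068), at 42.3 CPM, Siglech by 2.36, Tmem119 by 2.23, P2ry12 by 2.12 and Selplg by 2.02. So were the oligodendrocyte lineage receptor Gpr17 (2.26), the glycosidase Myorg (1.89), the astrocyte genes Btbd17 (1.56) and Cldn10 (1.49) and the myelin-associated gene Cmtm5 (1.6). Leaving out 5.0 nmol ended the calls of Ccl7 (-3.68), Ptx3 (-3.73), Socs3 (-3.08), Fosl1 (-3.23), Angptl4 (-3.01), Scgb3a1 (-3.41), Siglech (2.43), Tmem119 (1.99) and P2ry12 (1.66), leaving out 0.30 nmol those of P2ry12 (2.13) and Scgb3a1 (-3.53), leaving out 1.25 nmol that of P2ry12 (2.07), and leaving out 10 nmol that of Siglech (2.02). In the direct contrast Mt2 (-1.98, edgeR adjusted p = 0.0989), Scgb3a1 (-3.20), Siglech (2.81), Tmem119 (1.99), P2ry12 (1.5), Gpr17 (2.05) and Btbd17 (1.51) were not called. Hmox1 was lower by -4.23 ± 0.88 and just missed the threshold (edgeR adjusted p = 0.052), and passed without 1.25 nmol (-4.14), 10 nmol (-5.27) or saline (-3.96), but not without 0.30 or 5.0 nmol, with DESeq2 or in the direct contrast (-3.63, edgeR adjusted p = 0.100). Hpx (-1.74, edgeR adjusted p = 0.385), Timp1 (-3.25, edgeR adjusted p = 0.102) and Cxcl10 (-4.33, edgeR adjusted p = 0.131) did not pass. Cxcl10, which was lower at 10 than at 5.0 nmol, was called in the direct contrast with a smaller change (-2.19, edgeR adjusted p = 0.00731). Arg1 had 84 UMIs with heme-albumin and 0 with hemopexin, and the chitinase-like macrophage gene Chil3 32 and 0.

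As a comparison of those 2 libraries alone, Hmox1 had 244 UMIs in the striatal gene region with hemopexin against 2280 (12.1-fold lower; log2 -3.60, interval -3.80 to -3.41). Ptx3 was 11.4-fold lower, Ccl2 10.8-fold lower (log2 -3.43, interval -3.73 to -3.15), Timp1 6.53-fold lower and Mt2 3.88-fold lower, and Tnfrsf12a (-2.49), Tm4sf1 (-2.35), Anxa2 (-2.04), Tgm1 (-1.95) and Hspb1 (-1.87) were lower on the log2 scale. Hes5 was 8.13-fold higher (log2 3.02, interval 2.47 to 3.63), Tmem119 4.06-fold, Selplg 3.82-fold and P2ry12 2.90-fold. The lipid-sensing microglial receptor Trem2 was 2.37-fold higher (log2 1.25, interval 0.94 to 1.56), and the microglial genes Ly86 (1.29) and Olfml3 (1.22), Enpp2 (1.35), Ecrg4 (1.19), Ttr (1.12), Pltp (1.09) and Nkain4 (1.08) were higher too. All 16 microglia genes were higher, and their median of 0.87 lay at percentile 100 of the random lists (95% of them between -0.11 and 0.18). All 12 striatal neuron genes were higher as well (median 0.33, percentile 100), while reactive astrocyte genes had a median of -1.43 (percentile 0). Ependyma and choroid plexus (1.12), oligodendrocyte (0.50), oligodendrocyte precursor (0.50) and homeostatic astrocyte genes (0.22) were also higher, at percentiles 99.23 to 100. A higher level was thus not particular to microglia genes, and damage-associated microglia genes were lower (-0.31, percentile 0.04). All 4 erythrocyte genes tested were lower with hemopexin (median -5.12, percentile 0). Hbb-bs was at 114 CPM with heme-albumin and 3.46 with hemopexin, but also at 3.74 after saline and 121 in the untouched brain.

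The lists gave for the carrier in the striatal gene region (camera on the edgeR design) a microglia median of 1.14 (adjusted p = 4.63e-22, adjusted p = 0.245 with an estimated correlation) with 6 of 16 genes higher (13 adjusted over the list alone). Reactive astrocyte genes were lower in 5 of 24 (14 adjusted over the list alone, median -1.59, adjusted p = 2.18e-15, adjusted p = 0.245 with an estimated correlation). Matrix and wound genes were lower in 4 of 14 (9 adjusted over the list alone, median -1.18, adjusted p = 1.2e-17, adjusted p = 0.190 with an estimated correlation), NF-kB and cytokine genes in 4 of 19 (7 adjusted over the list alone, median -1.18, adjusted p = 1.59e-11, adjusted p = 0.264 with an estimated correlation), monocyte and macrophage genes in 3 of 14 (4 adjusted over the list alone, adjusted p = 4.48e-11) and NRF2 genes in 3 of 21 (6 adjusted over the list alone, median -0.46, adjusted p = 3.68e-09). Of 26 lists 16 passed camera, 0 with an estimated correlation and 1 with fry (oligodendrocyte precursors, 0.0413). Interferon genes had a median of -1.15 (adjusted p = 1.95e-05, adjusted p = 0.450 with an estimated correlation) with 0 called, against the fitted line. Between the 2 sections at 10 nmol themselves their median was -0.38, with 6 of 23 genes higher. Oligodendrocyte genes had a median of 0.68 (adjusted p = 0.000227, adjusted p = 0.397 with an estimated correlation) with 0 called and 6 up and 1 down adjusted over the list alone. Erythrocyte genes had a median of -5.97 (adjusted p = 2.27e-06, adjusted p = 0.245 with an estimated correlation) with 0 of 4 called and 4 lower adjusted over the list alone.

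Over whole sections edgeR called 0 genes for the carrier (smallest adjusted p = 0.157), with 994 at an unadjusted p below 0.05 and 91 by DESeq2 (25 higher). Hmox1 had a log2 difference of -2.76 ± 0.80 (edgeR adjusted p = 0.544) and Hpx one of -1.22 (edgeR adjusted p = 0.688). Between the 2 libraries Hmox1 was 4.88-fold lower with hemopexin (log2 -2.29, interval -2.37 to -2.21), and the heat shock genes Hspa1b and Hspa1a 6.84-fold and 5.08-fold lower, beside Timp1 (5.17-fold), Ptx3 (log2 -2.25), Ccn1 (-2.08), Ccl7 (-2.08), Atf3 (-1.89), Ccl2 (-1.78) and Nes (-1.77). The higher genes included Kl (2.23), Sostdc1 (1.81), Slc4a5 (1.37), Clic6 (1.35) and Kcnj13 (1.16), which are expressed in the choroid plexus, and Rtl8c (1.12). Of the lists, oligodendrocyte (median 0.44), striatal neuron (0.38), microglia (0.38) and ependyma and choroid plexus genes (0.37) were higher between the 2 libraries, at percentiles 99.99 to 100. The microglia list had a median of 0.42 (camera on the edgeR design, adjusted p = 1.19e-15, adjusted p = 0.323 with an estimated correlation) and reactive astrocyte genes one of -1.05 (adjusted p = 2.6e-21, adjusted p = 0.323 with an estimated correlation), with 6 and 10 genes adjusted over the list alone and 0 over all genes.

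Heme-hemopexin against saline asks what remained of the heme response on that carrier. Over whole sections edgeR called 2 genes, the mitochondrial leucyl-tRNA synthetase Lars2 (1.16 ± 0.09, edgeR adjusted p = 0.0479) and the myelin gene Bcas1 (1.07 ± 0.09, edgeR adjusted p = 0.0479), against 3161 at an unadjusted p below 0.05 and 943 by DESeq2. Neither was called without 0.30 nmol (1.21 and 1.06), 1.25 nmol (1.14 and 1.05) or 5.0 nmol (1.15 and 1.07), and fits without a section called 0 to 15 genes (15 without saline, 12 without 10 nmol). Against the dose line at 0 nmol, Hmox1 did not pass (0.61 ± 0.68, edgeR adjusted p = 0.626), nor did Hpx (-0.12). Between the sections themselves Hmox1 was at 39.8 CPM against 12.0 after saline, and in the striatal gene region at 33.8 against 2.91. In that region Timp1 was at 78.4 CPM against 3.33, Lcn2 at 172 against 7.07, Ptx3 at 15.8 against 1.04 and Tgm1 at 34.4 against 0.832, each with no replicate check. The section has the lower Q30 and saline does not, and scaling to total counts called 380 genes, 354 of them higher, with a shift of 0.17 in the median of all genes. Oligodendrocyte genes had a median of 0.90 (camera on the edgeR design, adjusted p = 1.19e-19, adjusted p = 0.336 with an estimated correlation; 10 adjusted over the list alone), striatal neuron genes one of 0.60 (adjusted p = 4.14e-08, adjusted p = 0.438 with an estimated correlation) and mitochondrial transcripts one of -0.63 (adjusted p = 1.14e-09, adjusted p = 0.437 with an estimated correlation).

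Position within the section was followed from the spot where Hmox1 was highest. Around it, at 1.25 nmol heme-albumin and above, microglial genes were low while NRF2 and reactive astrocyte genes were high. With heme-hemopexin, microglial genes were high around its own Hmox1 centre, but the centres lay in unlike tissue. Without RNA-poor spots, striatal neuron genes were at 4.32 of their far level at 10 nmol heme-albumin and 1.33 with heme-hemopexin. Oligodendrocyte genes were at 1.15 and 3.70. A microglia level above that of the far spots also occurred after saline. The microglia list within 500 µm, relative to spots beyond 2000 µm, was at 0.58 (0.53 to 0.64), 0.24 (0.20 to 0.28) and 0.36 (0.32 to 0.40) at 1.25, 5.0 and 10 nmol, and at 2.54 (2.44 to 2.65) with heme-hemopexin. It was at 0.90 (0.82 to 0.99) in the untouched brain, 1.38 (1.31 to 1.46) after saline and 1.01 (0.97 to 1.06) at 0.30 nmol, but in these 3 sections the Hmox1 centre lay in or near the cortical surface and not in the deep tissue. Between 500 and 1000 µm the ratio at 1.25, 5.0 and 10 nmol and with heme-hemopexin was 1.19, 0.60, 0.80 and 1.59. Complement and antigen presentation genes followed, at 0.87, 0.45, 0.50 and 2.67 in the same order, within 500 µm. NRF2 genes were at 2.5, 4.04, 2.89 and 2.37, and reactive astrocyte genes at 3.67, 6.65, 3.39 and 4.70. The neuron list was at 0.54, 0.73, 0.70 and 0.51. Interferon genes were at 2.12, 1.1, 0.80 and 4.60 and NF-kB and cytokine genes at 2.36, 2.33, 2.34 and 4.84. With RNA-poor spots left out, NRF2, reactive astrocyte, interferon and NF-kB and cytokine genes were at 1.73, 3.51, 4.36 and 7.52 after saline. At 0.30 nmol they were at 2.53, 3.49, 2.55 and 5.23. High reactive astrocyte, interferon and cytokine levels at the Hmox1 centre thus also occurred after saline, where it lay in or near the cortical surface. Oligodendrocyte genes were at 1.92, 1.52, 1.2 and 3.77, and damage-associated microglia genes at 1.48, 1.5, 1.07 and 2.10. These ratios have no replicate check.

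**Figure D4:**
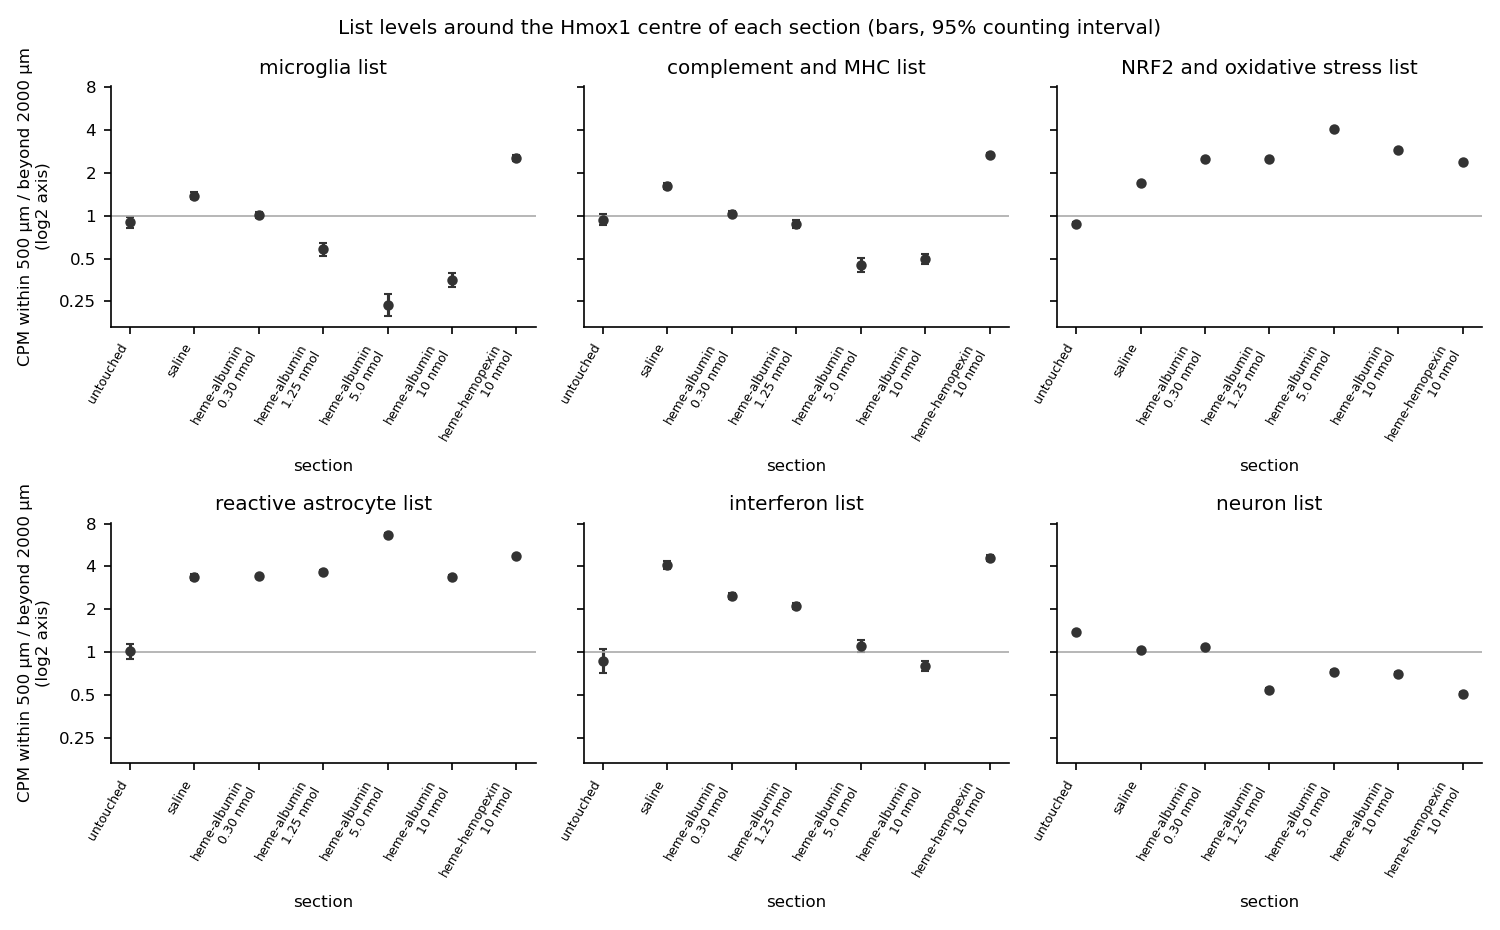
Ratio of list CPM within 500 µm of the Hmox1 centre to spots beyond 2000 µm (log2 axis) for 6 gene lists in the 7 sections, with 95% counting intervals. The microglia ratio was 0.24 at 5.0 nmol heme-albumin and 2.54 with heme-hemopexin.

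A cluster of RNA-poor spots was led by Btbd16, the hemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, the peptide gene Ucn2 and Gjb1. It held 14 spots (0.539%) at 0.30 nmol, 80 (3.30%) at 1.25, 143 (5.31%) at 5.0 and 204 (6.91%) at 10 nmol, against 1 spot (0.0341%) with heme-hemopexin, 1 (0.0360%) after saline and 0 in the untouched brain, which allows a share of up to 0.112%. Its median UMIs per spot at 1.25, 5.0 and 10 nmol were 5854.5, 3578 and 2918.5, against 17482, 15072 and 12198 in other spots. In the k-means clustering its counterpart, led by Gjb1 and Klk6 and holding Hmox1 among its leading genes, had 2.54%, 5.36%, 8.83% and 8.23% of spots at the 4 doses, 1.46% (43 spots) with heme-hemopexin and 0.288% after saline. Genes that respond to heme and hemoglobin genes define these clusters, so their shares are not a result apart from those genes, and no order of the doses is read from them. The striatal gene region made up 12.8%, 10.0%, 13.2%, 14.3%, 13.5%, 10.6% and 13.5% of spots in the order of the groups above, the cortical gene regions 29.0% to 30.8% and the myelin gene regions 7.09% to 10.0%. Thalamic genes marked 0% of spots at 1.25 nmol and 8.31% with heme-hemopexin.

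Saline against the untouched brain asks what the injection itself did. The chemokine genes Ccl4 and Ccl12 and Lcn2 were higher after saline, and oligodendrocyte genes such as Mobp were lower. The sections have a similar Q30 (97.1% and 97.2%), but the untouched one has 67.5% of reads under tissue, and with 1 section each the injection and the section cannot be told apart here. Of 13737 genes 1918 were higher and 1320 lower with edgeR, 1377 in all without 0.30 nmol, and scaling to total counts turned the share of higher genes from 59.2% to 7.78%, with a shift of -0.43 in the median of all genes. As 2 libraries, Lcn2 was 47.0-fold higher after saline (1084 against 15 UMIs; log2 5.55, interval 4.83 to 6.40), Ccl2 22.1-fold (272 against 8), Ccl4 21.9-fold (236 against 7), Ccl12 16.8-fold (1499 against 58), Ccl7 11.5-fold, Timp1 9.16-fold and the calgranulin S100a8 7.55-fold. Tgm1 had 102 UMIs against 0, at least 22.1-fold higher. Hmox1 was 3.01-fold higher (log2 1.59, interval 1.31 to 1.88), and the Hpx interval spanned 0 (0.70, -0.23 to 1.71). The fitted changes set the dose line at 0 nmol, and not the saline section itself, against the untouched section, so the heme-albumin sections enter them. With saline left out they rest on the heme-albumin sections alone, so that fit is no check on an effect of saline. Among the fitted changes, Lcn2 was at 6.56 (edgeR adjusted p = 0.00443), Ccl12 at 5.13 (edgeR adjusted p = 0.00443), Ccl4 at 5.07 and Lrrc17 at 2.99, and they were called without each section in turn, as were Mobp (-1.26, edgeR adjusted p = 0.00447), Plekhh1 (-1.40), Sec14l5 (-1.40), Mcam (-1.38) and Plekhg3 (-1.31). Ccl2 (5.81), Ccl7 (4.96), Timp1 (4.94), S100a8 (3.64) and Tubb6 (2.84) were called in the full fit but not without 0.30 nmol (5.90, 5.19, 4.95, 3.91 and 2.70), nor were Coro1b (-2.08, and -1.93 without it) and Galnt6 (-1.25, and -1.09 without it). Leaving out 1.25 nmol ended the call of the hormone gene Oxt (-1.34, and -1.36 without it), and leaving out saline that of Fam160b2 (-1.27, and -1.18 without it). Without the 10 nmol section Ccl7 (4.66), S100a8 (3.73) and Tubb6 (2.67) lost their calls too. Hist2h2aa1, which elsewhere separates the sections by Q30, differed between these 2 as well (28 against 155 UMIs, 8.51-fold lower after saline). It was called at -3.92 in the full fit (edgeR adjusted p = 0.0409) and at -2.95 without the 10 nmol section, but not without 0.30 nmol (-4.26) or 1.25 nmol (-3.59). Hmox1 did not pass in this fit (2.95 ± 0.89, edgeR adjusted p = 0.0525). Oxt (log2 -2.30 between the 2 libraries), Avp (-2.10), Agrp (2.24) and Pomc (1.89) are hypothalamic peptide genes, and Fmod (-2.11) and Slc13a4 (-1.84) meningeal ones.

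Of the lists, camera on the edgeR design gave NF-kB and cytokine genes 5 of 19 higher (10 adjusted over the list alone, adjusted p = 8.58e-07), reactive astrocyte genes 8 higher (9 adjusted over the list alone, adjusted p = 3.6e-06), oligodendrocyte genes 9 of 12 lower (10 adjusted over the list alone, adjusted p = 5.28e-10), mitochondrial transcripts 10 of 10 higher (adjusted p = 4.46e-12) and monocyte and macrophage genes 4 higher (adjusted p = 0.000334). Each had an adjusted p = 0.757 with an estimated correlation. Mitochondrial transcripts made up 13% of UMIs in the untouched and 19.9% in the saline section. Between the 2 libraries the medians of the NF-kB and cytokine, reactive astrocyte, oligodendrocyte and mitochondrial lists were 0.84, 0.24, -1.09 and 0.61, at percentiles 100, 100, 0 and 100 of the random lists.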

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

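The fits within sections, and the tests on a shared sequencing batch, on dilution near the Hmox1 centre and on saline against the untouched brain, were chosen after the results were seen. Those on section-wide change, on the order of the doses and on RNA-poor spots were written before.

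The dose response differed between the striatal and the cortical gene regions of the same sections, which is what drew attention to it. In a fit of striatal minus cortical regions within each section, edgeR called 304 genes, 169 with a more positive and 135 with a more negative dose slope in the striatal region. Among genes with a mean CPM of at least 5, Hmox1 led the former at 4.04 ± 0.21 on the log2 scale (edgeR adjusted p = 1.28e-10), with Ptx3 at 3.54, Cxcl1 at 2.92, Ccl2 at 2.92 ± 0.32 (edgeR adjusted p = 1.31e-05), Tnc at 2.86, S1pr3 at 2.82, Ccl7 at 2.77, Tnfrsf12a at 2.75, Rasl11a at 2.70 and Ccn1 at 2.66. Siglech (-2.64), Hes5 (-2.48 ± 0.26; edgeR adjusted p = 5.8e-06), Tmem119 (-2.34), Selplg (-2.21), P2ry12 (-2.19), Pld4 (-2.12), Cyp2s1 (-1.91), Ly86 (-1.89), Olfml3 (-1.88) and Aspa (-1.85) led the latter. Below that CPM, Arg1 had a larger fitted slope (5.39, edgeR adjusted p = 0.00439) and Sphk1 one of 3.49 (edgeR adjusted p = 0.000643). Arg1 had no UMIs in the striatal region after saline, so the size of its slope, and its rank above Hmox1, are uncertain. Of the 16 microglia genes 11 had a more negative slope in the striatal region (16 adjusted over the list alone; median -1.35; camera adjusted p = 1.13e-38; adjusted p = 0.152 with an estimated correlation), and 7 of 24 reactive astrocyte genes a more positive one (13 adjusted over the list alone; median 1.22). Mitochondrial transcripts, with negative medians in the striatal and the cortical regions, had a median of 0.06 (camera adjusted p = 0.635) in this fit. Of the 276 genes that rose in the striatal region 129 were also called here (3.45 for independent lists), and 57 of the 167 that fell (1.67), though both use the same sections. Without each section in turn 129 (without 10 nmol) to 290 genes were called, 141 without saline, and DESeq2 called 89.

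The carrier difference also differed between these regions, with 127 genes called in the same fit, 46 more positive and 81 more negative in the striatal region, and 91 (without 5.0 nmol) to 174 when a section was left out. DESeq2 called 28. Hmox1 was at -3.43 ± 0.20 (edgeR adjusted p = 1.16e-09), Socs3 at -2.66, Ccl2 at -2.40 and Tnfrsf12a at -2.17, and Hes5 at 2.24 (edgeR adjusted p = 4.89e-05), P2ry12 at 2.15, the phagocytic receptor gene Mertk at 1.95, Ly86 at 1.88, Tmem119 at 1.84 and Olfml3 at 1.63. Heme and iron genes had a median of 0.05 while the camera test pointed down (adjusted p = 0.00444; adjusted p = 0.155 with an estimated correlation).

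The first pattern weighed is the dose trend of the striatal gene region. A change shared by the whole section would cancel within sections. The slope within sections kept a median of 0.689 (bootstrap 95% over genes 0.650 to 0.731) of the striatal slope for the 276 rising genes. For the 167 falling genes it was 0.639 (0.557 to 0.756). These genes were picked by their striatal slope, which by itself raises this share, and the bootstrap resampled genes and not sections. How much of the trend is section-wide is thus not settled. For the 129 rising and 57 falling genes that were also called within sections, a section-wide change is not the whole cause. A batch shared by both sections at 10 nmol would move heme-hemopexin as far as the dose, whereas the median ratio of the changes was 0.329 (0.297 to 0.368), with 80 of 443 genes above 0.75, and these include Hist2h2aa1, Coro1b and Gstp1. Both changes are taken from the fitted line at 0 nmol, which need not equal the saline section, so the ratio can be too low. Hmox1, for example, was at 2.91 CPM after saline, 33.8 with heme-hemopexin and 409 at 10 nmol heme-albumin. The part of the trend that a shared batch could give is thus not settled. Among 100 drawn orders of the doses, 1, the real one, gave as many genes as the real 443 in the striatal region. The highest other, with saline and 0.30 nmol exchanged, gave 314. Over whole sections 2, the real one included, gave as many as the real 92. The other, the reversed order, called 264. It bends the dose scale the other way, and a ranked dose called 295. Few orders thus call as many genes as the real one. Reordering cannot tell the dose from depth, Q30 or single mice that happen to follow it, so chance differences between mice are not excluded. A response to heme stays open as a hypothesis found and tested on the same 7 sections, and differences between single mice remain untested.

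The second pattern is the low level of microglial genes around the Hmox1 centre at 5.0 and 10 nmol heme-albumin, against a high level with heme-hemopexin. The centres lay in unlike tissue, so the carrier and the site cannot be told apart in this contrast. Loss of RNA in the RNA-poor spots led by Btbd16 would leave normal levels once these are removed (21 within 500 µm at 5.0 nmol and 17 at 10 nmol), but without them the higher of the ratios at both doses was 0.350. The RNA-poor cluster led by Mbp was not removed, so loss of RNA in other spots was not tested. Dilution by abundant injury transcripts would lower other cell types alike, yet among the neuron, oligodendrocyte, endothelial and homeostatic astrocyte lists the smallest ratio to the microglia list there was 1.94. These lists were thus lowered less than microglia genes. They were chosen after the values were seen and also follow the tissue at the centre. Fibroblast and meningeal genes were as low as microglia genes at 5.0 nmol, so the test does not exclude dilution. Low ratios also occurred for other lists, but they depend on the tissue compared. At 5.0 and 10 nmol, ependyma and choroid plexus genes were at 0.17 and 0.097 of their far level. T and NK cell genes were at 0.20 and 0.36. With heme-hemopexin these lists were at 0.87 and 0.88, and in the untouched brain at 0.63 and 3.03. Without RNA-poor spots, far spots averaged 215 and 218 ependyma and choroid plexus UMIs at 5.0 and 10 nmol, against 75.7 with heme-hemopexin. Near spots averaged 22.7 and 28.3, against 63.7. The T and NK cell list holds Trbc2, a leading gene of a cortical cluster, and rested on 10 and 22 UMIs. Neither list by itself shows a loss that parallels microglia genes. Fibroblast and meningeal genes were at 0.22 and 0.46, but also at 0.50 with heme-hemopexin and 0.40 in the untouched brain, so their level at 10 nmol is not particular to heme-albumin. A loss of microglia, a fall of these transcripts in living microglia and displacement by entering cells may each give such values and were not separated.

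The third pattern is the difference of saline from the untouched brain. A batch of the saline section would leave heme-hemopexin, which has another Q30, at the untouched level, but its change from the untouched brain was a median 0.653 (0.639 to 0.667) of that of saline for the 1918 higher genes and 0.543 (0.514 to 0.572) for the 1320 lower genes, between the bounds set for either outcome. A batch of the untouched section would put all 6 injected sections on 1 side of it, as was so for 75.7% (2451) of the called genes, and as an effect of injection would too. These explanations and the injection cannot be told apart for these genes, since the untouched brain has 1 section, which is set apart by its reads under tissue (67.5%) but not by its Q30 (97.2%, against 97.1% after saline).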

How the results depend on the processing

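The linear and ranked dose in the striatal region, the direct contrast, the alternatives for the striatal carrier and within-section results, and the profiles without RNA-poor spots or with a centre below the cortex were chosen after seeing the data. No paired analysis was possible because each group has 1 section, so the within-section fit pairs regions and not groups. Where no cause is named, the cause was not tested. Whole-section dose calls (92) became 700 with DESeq2, 388 with total counts, 157 with no filter, 15 with a linear and 295 with a ranked dose, 23 with the untouched brain as dose 0, and 0 to 202 without a section. Striatal dose calls (443) became 249 with DESeq2, 229 with a linear dose and 117 to 362 without a section, and stayed within 1.5 times with total counts (606, 90.6% rising against 62.3%, median shift 0.19), a ranked dose (399), no filter (563), k-means (473) and no centring (442). Cortical dose calls (17) became 180, 66, 88, 2 and 73 with DESeq2, total counts, no filter, k-means and no centring, and 9 to 111 without a section. Myelin dose calls (120) became 32 with DESeq2, 72 with k-means and 59 to 139 without a section. Carrier calls over whole sections (0) became 91 with DESeq2, 3 with a ranked dose and 0 to 1 without a section. Striatal carrier calls (144) became 95 with DESeq2, 230 with no filter, 3 with a linear dose, 53 in the direct contrast and 51 to 272 without a section. Heme-hemopexin against saline (2) became 943, 380, 118, 117 and 0 with DESeq2, total counts, no filter, a linear and a ranked dose, and 0 to 15 without a section. Saline against untouched (3238) became 7161 with total counts and 1377 to 3145 without a section. Within-section dose calls (304) became 89 with DESeq2 and 129 to 290 without a section, and within-section carrier calls (127) 28 with DESeq2, 223 with no filter and 91 to 174 without a section. Shares of spots with a Hmox1 UMI, in the order untouched, saline, 0.30, 1.25, 5.0 and 10 nmol and heme-hemopexin, were 1.96%, 2.93%, 8.41%, 20.4%, 26.9%, 34.8% and 12.7% at 5000 UMIs and 4.55%, 8.27%, 15.6%, 34.8%, 42.2%, 46.5% and 22.0% unthinned, where deeper spots count more often. The microglia ratio near the centre was 1.57 for heme-hemopexin and 0.504 at 10 nmol with a smoothing radius of 1000 µm, 0.320 at 5.0 nmol with 300 µm, and 2.37 for heme-hemopexin with spots beyond 1500 µm as reference, each on the same side of 1 as in the main setting. Signs reversed for Hpx against saline (-0.12, but 0.040 with total counts and -0.30 to 0.024 without a section) and Hmox1 against saline (0.61, but -0.14 with a linear dose). Leaving out a section also reversed Hpx in the striatal dose trend (-0.13 to 2.06) and, in the myelin dose trend, S100a9 (-0.14 to 5.17), Hbb-bs (-0.83 to 7.43), Hba-a1 (-0.72 to 7.79) and Pmch (-5.11 to 0.070). Of the other values of named genes, 445 kept direction and side of the threshold when a section was left out, 203 lost and 6 gained the call, and under other settings 750 kept both, 147 lost and 11 gained it. Of the ratios of the other lists near the centre, 49 moved beyond counting error and 18 did not with a radius of 1000 µm, 32 and 35 with 300 µm, 33 and 34 with the nearer reference, 19 and 48 without RNA-poor spots and 23 and 44 with a centre below the cortex. Of the region shares, 14 of 21 moved with k-means, 11 with resolution 0.5 and 9 with no centring. Sections at 0 UMIs for Arg1, Chil3 and Tgm1 leave only bounds at this depth.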

Other observations

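The profiles with the centre placed below the cortex were chosen after the results were seen, and so was the look at the carrier in the myelin gene regions. In these regions, the heme-hemopexin section had fewer interferon and more microglial transcripts than the fitted heme-albumin line at 10 nmol. No direct contrast of the sections at 10 nmol was made here. In the striatal gene region the line gave a larger interferon difference than the sections themselves (median -0.38). Around the Hmox1 centre, without RNA-poor spots, interferon genes were at 4.53 of their far level with heme-hemopexin and 0.853 at 10 nmol heme-albumin. EdgeR called 16 genes higher and 56 lower (838 unadjusted). The phagocyte genes Adgre1 (3.04), Fcrls (1.57; edgeR adjusted p = 0.000131) and Trem2 (1.52; edgeR adjusted p = 0.000258) and the chemokine Ccl5 (2.64; edgeR adjusted p = 9.76e-09) were higher. The interferon-induced genes Ifit1 (-3.67; edgeR adjusted p = 3.08e-06) and Cmpk2 (-3.25) and the chemokine Ccl7 (-2.86; edgeR adjusted p = 4.08e-09) were lower. The interferon list was lower in 12 of 25 genes (16 adjusted over the list alone; median -1.67; camera adjusted p = 6.46e-24; adjusted p = 0.235 with an estimated correlation). The microglia list was higher in 2 of 16 (12 adjusted over the list alone; median 0.81; camera adjusted p = 4.74e-16; adjusted p = 0.235 with an estimated correlation). The regions join clusters of unequal depth, and at 10 nmol heme-albumin the RNA-poor one was the larger. The edgeR p-values in these regions rest almost wholly on a variance pooled over genes (prior of 171 against 3 residual degrees of freedom). Small p-values here thus say little about how a single gene varies between sections.

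After saline and at 0.30 nmol the highest Hmox1 lay in or near the cortical surface, along the upper part of the section. With the centre placed below the cortex, the microglia list within 500 µm was at 1.80 after saline and 1.57 at 0.30 nmol relative to the far spots. Interferon genes were at 0.82 and 7.16 and reactive astrocyte genes at 1.19 and 5.70, so at 0.30 nmol a deep site with high interferon and astrocyte genes was present without the low microglial level of the higher doses.

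In the striatal gene region, edgeR called 21 genes higher and 29 lower for heme-hemopexin against saline (1666 unadjusted). Of the higher genes, Hist2h2aa1 (9.53), Coro1b (3.47), Nme2 (2.80) and Gstp1 (2.51) were high in both sections with the lower Q30.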
